A study of Mus musculus with 16 samples.

How the data were processed

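RNA from the hippocampus of male mice of the SAM/P-8 strain and the SAM/R-1 strain, on a control diet or the same diet with CCH, was hybridised to 16 one-colour whole mouse genome arrays, 4 per group. Per the labels the RNA integrity number was above 9. The deposited files of the single arrays hold the processed signal of each spot as an intensity, per the file headers made with Agilent Feature Extraction 9.5.3.1, which subtracts background and removes trends within an array. They also hold the median signal of the spot and of its local background, likewise an intensity per the file headers, and flags of the scanner software of the kind other than a measured value per the file headers, which mark spots as well above background, non-uniform or saturated. The authors' table of values is on a log2 scale and centred so that the median of each probe over the 16 arrays is 0. After centring, the scanner values correlated with it at 0.9997 or more on each array, with column medians between -0.04 and 0.04.

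Groups were taken from the labels. Per the file headers the arrays lay on 4 slides with 1 group each, and the replicate number equalled the position on the slide on 16 of 16 arrays, so a slide term could not be fitted. Each array had 45018 spots, 43379 of them non-control, and 28920 to 33333 of these were well above background. The mean share ± SD was 71.1 ± 0.768% in SAM/P-8 CCH, 68.5 ± 1.83% in SAM/P-8 control, 73.9 ± 2.50% in SAM/R-1 CCH and 71.8 ± 1.29% in SAM/R-1 control. Over all arrays 187 spots were marked non-uniform and left out, and 2 were saturated. Replicates of a group correlated between 0.987 and 0.997. The number of arrays limits the precision.

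The processed signal was taken as log2, the 75th percentile of the non-control probes of the array was subtracted, and spots of one probe were averaged. Of 41174 non-control probes, 29009 were kept because they were well above background on all 4 arrays of at least 1 group, and 12165 were left out. Among the probes kept, 26426 were well above background on all 16 arrays and 92 values were missing. The files carry no gene names, so probes were named through the RefSeq accession given for them: 24844 probes received a name and 16330 did not, and the latter were tested and counted but not named. A gene was represented by the probe with the highest mean over the 16 arrays, which gave 13459 genes. Positions are not given, because the genome build of the array design differs from that of the table used for names, which served only for names and the order of genes.

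limma 3.58.1 in R 4.3.3 fitted a mean per group over all 16 arrays with 12 residual degrees of freedom and a prior of 2.32, and 6 contrasts were tested: the strain difference on each diet, the CCH effect in each strain, the CCH effect averaged over the strains, and the strain by diet interaction. P-values were adjusted by Benjamini-Hochberg over the probes kept, with a threshold of 0.05. Of 42 gene lists, fixed before the data were examined and holding 930 entries of which 881 had a probe, those with at least 5 genes were tested by camera with a preset correlation of 0.01, adjusted over 42 lists in each contrast, and again with an estimated correlation and with fry. A list score is the mean over the genes of a list after subtracting each gene's mean over the 16 arrays. Lists can share genes, such as Per1 in the clock and glucocorticoid-responsive lists. The relation between the strain difference and the CCH effect in SAM/P-8 was set against 100 simulations without effects, because both use the SAM/P-8 control arrays. The overlap of their genes was also simulated without effects, after the result was seen. There each gene had the same spread, and lists of the observed sizes were taken by rank of the difference.

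Genes were named by a rule fixed before the data were examined. Per contrast, among probes with a symbol past the threshold whose 4 and 4 arrays did not overlap, the 10 largest increases and the 10 largest decreases were named, or all if fewer. For the strain difference on the CCH diet, the average and the interaction 5 and 5 were named, the last 2 without the condition on overlap. Per list described, up to 4 members past the threshold with the largest difference were named, or the 2 with the smallest p where none passed. Some genes that the rule names are not reported here. Genes shared between the strain difference and the CCH effect, between the CCH effects of the strains or of opposite strain difference on the 2 diets were named because the counts called for it, after their values were seen. Where a group had 0 arrays well above background, the fold is a lower bound against the lowest signal well above background on those arrays. Where the lower group had 1 or 2 such arrays and the text says at least, each of its values below that lowest signal was raised to it first. Signs of list members were set against those of genes in the same 1 of 20 brightness classes, after the result was seen.

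The same steps were tested on simulated data with 200 of 28943 probes changed and the measured spread. In the CCH effect in SAM/P-8, 7.50% of probes changed by 1.2-fold, 70% of those changed by 1.5-fold and 93% of those changed by 2-fold were recovered, and in the interaction 0%, 54% and 79%. A shift of 0.2 in 21 genes was called by camera in 10 of 10 simulations for the CCH effect in SAM/P-8 and in 5 of 10 for the interaction. The simulated genes varied independently of each other. The simulations therefore cannot show how camera behaves where the genes of a list vary together.

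Alternatives planned before the data were examined were quantile normalization, normexp background correction with an offset of 50, no filter on dim probes, only probes well above background on all 16 arrays, the authors' table of values, the replicate number as a block, only the groups compared in the fit, eBayes with trend and robust, 1 probe per gene, a minimum of 1.5-fold, array weights, the other probes of a gene, the estimated correlation, fry, split control arrays, and leaving out each array in turn. The files hold no mean signal, so normexp used the median signal in place of the planned mean signal. Normexp together with trend and robust, and the choroid plexus and striatum scores as covariates, were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.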

Results

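Gene expression in the hippocampus of male mice of 2 inbred lines, SAM/P-8 and SAM/R-1, was measured on 16 one-colour Agilent arrays. SAM is the senescence-accelerated mouse, bred from AKR/J stock per the labels, and the P and R lines are known as its senescence-prone and senescence-resistant branches. From 8 weeks of age the mice ate for 8 weeks either a standard rodent diet or the same diet with 0.1% CCH, coral calcium hydride. Each of the 4 groups held 4 arrays. The labels number the replicates and do not say whether each array came from a separate animal, so p-values measure only the spread between these samples. Each group lay on 1 slide of its own, so slide and group cannot be told apart in any comparison that follows. Between 28920 and 33333 of the 43379 non-control spots per array were well above background, and the number of arrays limits the precision. The first principal component held 42.6% of the variance and separated the strains, with scores from -43.6 to -24.6 in SAM/P-8 and from 27.8 to 36.5 in SAM/R-1. Differences are log2 values ± SE from limma with n = 4 and 4 unless stated otherwise. Splits of the same arrays were also counted by whether they gave as many gene lists past the threshold as the real groups. With the real split included, 33 and 30 of 35 did so for the strain differences on the control and the CCH diet. Counted likewise, it was 21 and 10 of 35 for the CCH effects in SAM/P-8 and SAM/R-1, and 18 and 85 of 100 for the average and the interaction.

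On the control diet some of the largest strain differences lay in genes near background in one strain. Ccl19, Ppp1r1a and Prdm16 were well above background on all arrays of both. Tyk2, Lefty1 and Prdm16 had a single probe here, so a strain variant under it cannot be told apart from a different level. Tyk2, a Janus kinase that relays interferon signals, was at least 65.5-fold higher in SAM/P-8 than in SAM/R-1, where the probe was not well above background on any array (adjusted p = 9.73e-13). Trim12a, a TRIM family gene, was at least 40.1-fold higher (adjusted p = 1.72e-13), and Ccl19, a chemokine that attracts lymphocytes and dendritic cells, was 67.1-fold higher (6.07 ± 0.22, adjusted p = 4.89e-11). In the other direction Lefty1, a secreted inhibitor of Nodal signalling, was at least 62.7-fold lower in SAM/P-8 (adjusted p = 2.08e-11). Ppp1r1a, an inhibitor of protein phosphatases, was 8.69-fold lower (-3.12 ± 0.10, adjusted p = 9.63e-12), and Prdm16, a transcriptional regulator, was 11.6-fold lower (-3.54 ± 0.20, adjusted p = 1.19e-08).

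Other genes among the largest increases were Oas1a, at least 5.71-fold, Plac8, at least 3.59-fold, Abcb1a, the efflux pump of the blood-brain barrier, at least 4.40-fold, Tspan11, a tetraspanin, at least 2.97-fold, and Trim30d, at least 1.99-fold with 3 of 4 SAM/P-8 arrays well above background. Tmem40 was at least 8.21-fold higher with 2 of 4 SAM/R-1 arrays well above background, and Usp18, an interferon-induced protease, at least 6.20-fold with 1 of 4. The largest decreases further included Gdpd5, a phosphodiesterase of glycerophospholipids, 13.8-fold, and Zfp551, a zinc finger gene, 7.83-fold. Capg, an actin-capping protein, was at least 10.4-fold lower with 1 of 4 SAM/P-8 arrays well above background. Trub1, a pseudouridine synthase, was 5.49-fold lower, but its 1 other probe gave -0.30 and did not pass (limma adjusted p = 0.0751). Lefty2 was at least 1.64-fold lower. Slc7a9, an amino acid transporter, and Akap4, a scaffold of the sperm tail, were lower by sizes not measured. Slc7a9 stood at -2.92 in SAM/R-1 control replicate 4, apart from the 3 others, and without that array its bound of 1.56-fold fell to 0.962-fold. All of these passed the test, with adjusted p from 4.37e-13 for Zfp551 to 0.00326 for Slc7a9.

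**Figure D1:**
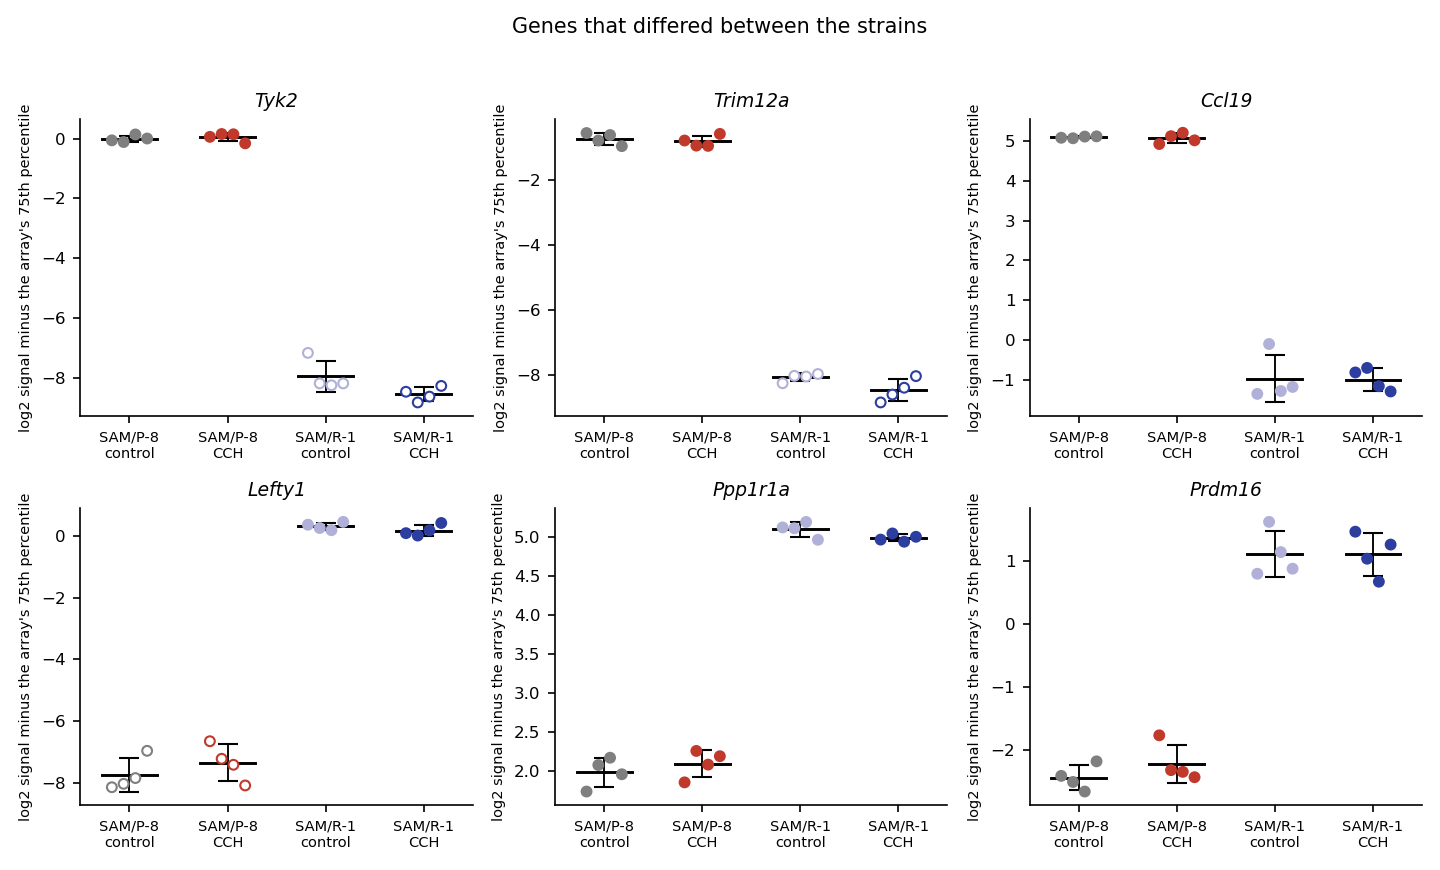
Log2 signal minus the array's 75th percentile for 6 genes that differed between the strains. Each point is 1 array, open where the probe was not well above background, with the mean and SD of 4 arrays in black, and Tyk2, Trim12a and Lefty1 were well above background in all arrays of one strain and in none of the other, on both diets.

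Interferon response genes were higher in SAM/P-8 as a group: of 21 measured, 17 were higher and 0 lower, and 18 were higher when adjusted over the list alone. The list's median difference was 0.96, with Oas1a, an antiviral oligoadenylate synthetase, Oas2, at least 2.19-fold higher with 3 of 4 SAM/P-8 arrays well above background, and Ifit1, at least 4.10-fold higher with 1 of 4 SAM/R-1 arrays well above background, in front. For interferon genes camera gave an adjusted p of 2.00e-13 (adjusted p = 0.467 with an estimated correlation). Of 20 endothelial and pericyte markers, 13 were higher and 0 lower, with 17 adjusted over the list alone and a median of 0.52. Ly6a was higher by 1.49 ± 0.18, the pericyte gene Rgs5 by 0.92 ± 0.10 and the VEGF receptor Flt1 by 0.78 ± 0.12. For endothelial genes camera gave an adjusted p of 3.58e-11 (adjusted p = 0.467 with an estimated correlation). Antigen presentation genes went both ways, with 6 of 14 higher and 2 lower, the same numbers adjusted over the list alone. For antigen presentation genes camera gave an adjusted p of 0.0154 (adjusted p = 0.995 with an estimated correlation). Psmb8 and Psmb9, subunits of the immunoproteasome, were higher by 0.80 ± 0.10 and 0.74 ± 0.06, and H2-T23 by 0.71 ± 0.12, while H2-DMb1 was lower (-0.63 ± 0.19). Among 24 heat shock and chaperone genes 4 were higher and 0 lower, 8 adjusted over the list alone, including Hspb1 (1.03 ± 0.32), Sdf2l1 (0.46 ± 0.13), the unfolded protein response factor Xbp1 (0.37 ± 0.08) and Hsp90ab1 (0.35 ± 0.06). The camera adjusted p of that list was 0.0101 (adjusted p = 0.995 with an estimated correlation).

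Meningeal and fibroblast markers, which come from tissue next to the hippocampus, had a median of 0.61, with 1 of 20 genes past the threshold, Islr (0.60 ± 0.14, but 0.35 and not past it by its other probes), and 10 higher and 2 lower adjusted over the list alone. For meningeal genes camera gave an adjusted p of 0.0154 (adjusted p = 0.995 with an estimated correlation). Pituitary and hypothalamic hormone genes were lower, with 2 of 11 past the threshold, the hormone precursor Pomc (-0.56 ± 0.05) and Lhb (-0.28 ± 0.08), and 4 adjusted over the list alone. For hormone genes camera gave an adjusted p of 0.0304 (adjusted p = 0.995 with an estimated correlation). Leaving out 1 array ended 3 of these calls. That of the meningeal list ended without SAM/P-8 control replicate 1 (mean from 0.52 to 0.28, adjusted p = 0.325) and without SAM/R-1 control replicate 4 (0.44, adjusted p = 0.0917). That of the hormone list ended without SAM/R-1 control replicate 3 (mean from -0.37 to -0.17, adjusted p = 0.0903) and without SAM/P-8 control replicate 3 (-0.33, adjusted p = 0.0507). That of antigen presentation ended without SAM/P-8 control replicate 1 (mean from 0.24 to 0.18, adjusted p = 0.0605) and without SAM/R-1 control replicate 4 (0.21, adjusted p = 0.0507). In total limma called 4004 of 29009 probes, 1744 higher and 2260 lower in SAM/P-8, which came to 1726 of 13459 genes. With the background estimated by normexp the count fell to 962, and 44 of 2187 genes had called probes of opposite direction. Of the 235 genes called with a difference of at least 2-fold, 191 had a single probe here, so for these a strain variant under the probe cannot be told apart from a different level. Tyk2, Lefty1, Prdm16, Gdpd5, Zfp551, Capg and Oas1a were among them.

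On the CCH diet Tyk2, Trim12a, Ccl19 and Lefty1 were again among the largest strain differences. Tyk2 was at least 95.4-fold higher in SAM/P-8 (adjusted p = 5.04e-13), Trim12a at least 52.9-fold (adjusted p = 7.19e-14), Ccl19 66.5-fold (6.06 ± 0.22, adjusted p = 5.04e-11) and Oas1a at least 7.52-fold (adjusted p = 2.30e-07). Vmn1r214, a vomeronasal receptor gene, was at least 11.0-fold higher (n = 3 and 4, adjusted p = 5.02e-05). Lefty1 was at least 73.0-fold lower (adjusted p = 4.98e-11), Gdpd5 13.2-fold (-3.72 ± 0.20), Capg 11.8-fold (-3.56 ± 0.15, with 1 of 4 SAM/P-8 arrays well above background), Prdm16 9.97-fold (-3.32 ± 0.20) and Pnlip, pancreatic lipase, at least 2.70-fold (adjusted p = 1.98e-06). The 2 strain differences shared no arrays: over 13458 genes, which are not independent replicates, they correlated with Pearson's r = 0.779 and Spearman's rho = 0.651. Of these, 1019 genes were called in both in one direction against 3 in opposite directions (Foxe3, Mob3a and Nat3, named because they were the exceptions).

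Interferon response genes were again higher in SAM/P-8, 14 of 21 with 0 lower and 18 adjusted over the list alone, with a median of 1.10. For interferon genes camera gave an adjusted p of 1.29e-14 (adjusted p = 0.563 with an estimated correlation). Usp18 was at least 9.26-fold and Ifit1 at least 6.40-fold higher, each with 2 of 4 SAM/R-1 arrays well above background, and Oas2 was at least 2.94-fold higher. SAM/P-8 CCH replicate 4 had an interferon score of 1.36 against 0.31 to 0.51 on the other 3 arrays of its group. Without it the bounds fell to 6.39-fold for Usp18, 4.11-fold for Ifit1 and 2.23-fold for Oas2. Of 20 endothelial and pericyte markers 7 were higher and 10 adjusted over the list alone, with Abcb1a at least 7.07-fold, Ly6a 2.63-fold, Pdgfrb 1.63-fold and Rgs5 1.62-fold higher. For endothelial genes camera gave an adjusted p of 1.03e-06 (adjusted p = 0.978 with an estimated correlation). Microglial markers were higher, 9 of 19 with 0 lower and 9 adjusted over the list alone, among them Gpr34 (0.46 ± 0.13), Itgam (0.43 ± 0.08), Ly86 (0.43 ± 0.10) and the cathepsin gene Ctss (0.34 ± 0.10). Itgam turned to -0.02 with normexp. For microglial genes camera gave an adjusted p of 0.00138 (adjusted p = 0.978 with an estimated correlation). Antigen presentation genes had 7 of 14 higher and 1 lower, 7 and 4 adjusted over the list alone. They included H2-T23 (0.78 ± 0.12), Psmb8 (0.77 ± 0.10), Psmb9 (0.67 ± 0.06) and H2-D1 (0.65 ± 0.12, but -0.01 by its other probes). For antigen presentation genes camera gave an adjusted p of 0.0146 (adjusted p = 0.978 with an estimated correlation). The mean of that list went from 0.15 to 0.23 without SAM/P-8 CCH replicate 3.

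Of 37 cytoplasmic ribosomal protein genes 5 were lower and 0 higher, 7 adjusted over the list alone, with a median of -0.09 and Rpl30 (-0.37 ± 0.07), Rps15 (-0.33 ± 0.06), Rpl13 (-0.22 ± 0.05) and Rpl37 (-0.18 ± 0.05) in front. For ribosomal genes camera gave an adjusted p of 7.85e-04 (adjusted p = 0.978 with an estimated correlation). Of 37 genes of the respiratory chain and ATP synthase 8 were lower and 0 higher, 11 adjusted over the list alone, with a median of -0.10. They included Ndufa2 (-0.22 ± 0.04), Atp5d (-0.21 ± 0.05) and Atp5o (-0.19 ± 0.05). For respiratory genes camera gave an adjusted p of 0.00106 (adjusted p = 0.978 with an estimated correlation). Both calls ended with quantile normalization. Meningeal markers were higher with 2 of 20 past the threshold, Col3a1 (1.13 ± 0.35) and Islr (0.56 ± 0.14), and 6 adjusted over the list alone. For meningeal genes camera gave an adjusted p of 0.00106 (adjusted p = 0.978 with an estimated correlation). Striatal markers had a median of 1.01 and dopamine signalling genes one of 0.80, with 0 genes of either list past the threshold and 0 adjusted over the list alone. Camera gave them adjusted p of 0.0146 and 0.0231 (adjusted p = 0.978 for each with an estimated correlation). Their members with the smallest p were Foxp1 (0.46 ± 0.19) and Ido1 (2.13 ± 0.92), and Adcy5 (0.84 ± 0.42) and Slc18a2 (0.60 ± 0.32). That shift lay in SAM/P-8 CCH replicate 4, whose striatum score was 3.68 against -0.43 to 0.15 on the other 3 arrays of its group, and without it the mean of the striatum list turned from 0.94 to -0.04 and both calls ended. In total 3909 probes were called, 1856 higher and 2053 lower, in 1703 genes, and 840 with normexp. Of the 1856 higher probes 1595 kept their direction with normexp, and of the 2053 lower ones 2053. On the control diet 1741 of 1744 higher probes kept it.

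The next comparison asked what differed between the CCH and the control diet in SAM/P-8. As a list the clock genes rose: 17 of 19 had positive differences, where genes of equal brightness would give 8.18, with a median of 0.27. Ciart, a repressor of the circadian clock, rose 1.53-fold (0.61 ± 0.11, adjusted p = 0.0215) as the 1 gene past the threshold, with 7 adjusted over the list alone. For clock genes camera gave an adjusted p of 3.82e-07 (adjusted p = 0.178 with an estimated correlation). Immediate early genes, which neurons switch on with activity, rose as a list with a median of 0.31, 0 of 24 genes past the threshold and 6 adjusted over the list alone. Egr4 stood at 0.64 ± 0.15 and Nr4a1 at 0.62 ± 0.17, with adjusted p of 0.0617 and 0.0880. For immediate early genes camera gave an adjusted p of 3.82e-07 (adjusted p = 0.607 with an estimated correlation). Respiratory chain and ATP synthase genes fell, 36 of 37 with negative differences, where genes of equal brightness would give 29.9, and a median of -0.13. Of them Ndufa2 (-0.28 ± 0.04), Ndufa4 (-0.21 ± 0.04) and Cox4i1 (-0.21 ± 0.04) passed the threshold, with 17 adjusted over the list alone. For respiratory genes camera gave an adjusted p of 1.32e-10 (adjusted p = 0.607 with an estimated correlation). Cytoplasmic ribosomal protein genes fell by a median of 0.13, 36 of 37 with negative differences against 30.2 at equal brightness, 0 past the threshold and 18 adjusted over the list alone. Rps9 stood at -0.21 ± 0.05 and Rpl37 at -0.22 ± 0.05. For ribosomal genes camera gave an adjusted p of 5.22e-12 (adjusted p = 0.607 with an estimated correlation).

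Outside these lists Kcnh5, a voltage-gated potassium channel, was 1.65-fold higher on the CCH diet in SAM/P-8 (0.72 ± 0.11, adjusted p = 0.0135). Cenph, a centromere protein, was 1.59-fold higher (0.67 ± 0.13) and Zfp516 1.56-fold (0.64 ± 0.13). The slide cannot be told apart from the diet for any of these genes or those that follow. Misp, a spindle protein, was 2.00-fold higher and Vipr1, a receptor for vasoactive intestinal peptide, higher by 0.59 ± 0.12. Each had 3 of 4 control arrays well above background. The hair keratin Krt35 and Vmn1r214 were at least 3.36-fold and 5.60-fold higher (n = 3 and 4 for each). For both, 3 of 4 control arrays were not well above background, so their full sizes are not measured. Asb9 and the acetyltransferase Nat3, with 0 control arrays well above background, were at least 2.39-fold and 1.53-fold higher, and Nat3 at least 1.26-fold without SAM/P-8 CCH replicate 1. AY761185 fell 7.63-fold (-2.93 ± 0.24, adjusted p = 1.67e-05), the olfactory receptor gene Olfr1263 3.56-fold (-1.83 ± 0.25), Adamts14, a protease that processes procollagen, 2.34-fold (-1.23 ± 0.15, adjusted p = 0.00151), and Tfap2e, a transcription factor, 2.28-fold (-1.19 ± 0.25, n = 3 and 4). Stc1, stanniocalcin, a secreted protein of calcium and phosphate handling, fell 1.58-fold (-0.66 ± 0.08, adjusted p = 0.00151), but its other probe gave 0.22. Mc2r, the receptor for corticotropin, fell 1.67-fold (-0.74 ± 0.14), the neuropeptide gene Npb 1.58-fold (-0.66 ± 0.12), and the endocytic receptor gene Lrp2 1.44-fold (-0.53 ± 0.10), with 1 other probe that did not pass (-0.32, adjusted p = 0.146). Nr5a2, a nuclear receptor, and Accsl were lower by sizes not measured, with 0 CCH arrays and only 1 and 2 of 4 control arrays well above background, and Accsl turned to 0.02 with normexp.

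**Figure D2:**
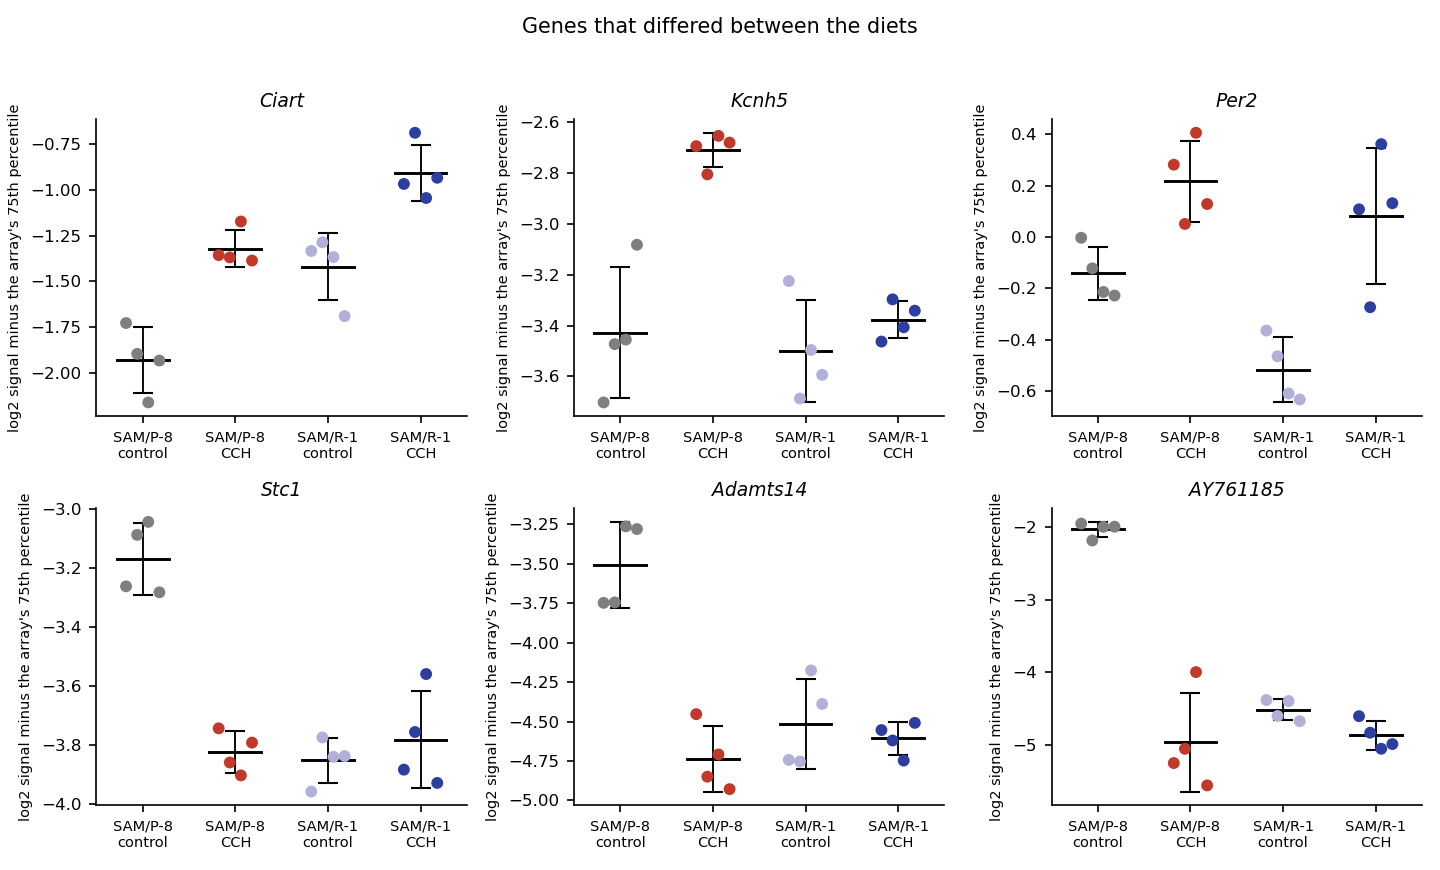
Log2 signal minus the array's 75th percentile for 6 genes that differed between the diets in SAM/P-8 or, for Per2, on average over the strains. Each point is 1 array, well above background throughout, with the mean and SD of 4 arrays in black, and AY761185 lay at -2.03 in SAM/P-8 on the control diet and between -4.96 and -4.51 in the other 3 groups, as group means.

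Further lists shifted in SAM/P-8 with CCH by smaller steps. Proteasome genes fell by a median of 0.09, 26 of 27 with negative differences against 20.5 at equal brightness, 0 past the threshold and 2 adjusted over the list alone. Psmb7 stood at -0.28 ± 0.06 and Psmb4 at -0.20 ± 0.05. For proteasome genes camera gave an adjusted p of 4.02e-05 (adjusted p = 0.619 with an estimated correlation). This call and that of the oligodendrocyte precursor list ended with quantile normalization. Cholesterol synthesis genes rose with 1 of 22 past the threshold, Insig1 (0.43 ± 0.08, but 0.21 and not past it by its other probes), and 3 adjusted over the list alone. For cholesterol genes camera gave an adjusted p of 6.25e-04 (adjusted p = 0.619 with an estimated correlation). In the senescence and DNA damage list Tert, the telomerase catalytic subunit (0.48 ± 0.09, with 3 of 4 control arrays well above background), and Terf1, a telomere-binding protein (0.35 ± 0.07), rose as 2 of 22 genes, with 5 higher and 1 lower adjusted over the list alone. For senescence genes camera gave an adjusted p of 0.0149 (adjusted p = 0.178 with an estimated correlation). Glucocorticoid-responsive genes rose with 0 of 15 past the threshold and 2 adjusted over the list alone. Per1, also in the clock list, stood at 0.48 ± 0.11 and Pdk4 at 0.38 ± 0.10. For glucocorticoid-responsive genes camera gave an adjusted p of 7.93e-04 (adjusted p = 0.619 with an estimated correlation). Heat shock genes (Hspa1b 0.86 ± 0.33, Hspa1a 0.67 ± 0.31) and precursors of oligodendrocytes (Tmem100 0.24 ± 0.10, Lhfpl3 0.21 ± 0.11) rose as lists with 0 genes past the threshold and 0 adjusted over the list alone. Camera gave both lists adjusted p of 0.00418 and 0.0301 (adjusted p = 0.619 for each with an estimated correlation).

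Markers of other tissues moved with the diet in SAM/P-8 too. Striatal genes had a median of 0.98 and dopamine signalling genes one of 0.66, with 0 of 16 and 0 of 19 past the threshold and 0 adjusted over the list alone. Camera gave adjusted p of 1.06e-04 and 0.00459 (adjusted p = 0.619 and 0.637 with an estimated correlation). Ido1 stood at 2.04 ± 0.92 and Maoa at -0.10 ± 0.04. Gpr6, with 0 of 4 control arrays well above background, had an adjusted p of 0.188. Without SAM/P-8 CCH replicate 4 the mean of the striatum list went from 1.14 to 0.17 and that of the dopamine list from 0.73 to 0.07, and both calls ended, as did those of the heat shock, oligodendrocyte precursor and meningeal lists. Meningeal markers rose with 0 of 20 past the threshold or adjusted over the list alone (Col6a2 0.45 ± 0.14, Col6a1 0.37 ± 0.21). Red blood cell genes fell with 0 of 7 past the threshold and 2 adjusted over the list alone (Slc4a1 -1.86 ± 0.52, Bpgm -0.20 ± 0.07). The camera adjusted p of these lists was 0.00675 and 0.0169 (adjusted p = 0.637 and 0.619 with an estimated correlation). The red blood cell scores of SAM/P-8 control replicates 1 to 4 were 0.92, 1.49, -0.15 and -0.00. Without replicate 2 the mean of that list went from -0.76 to -0.45 (adjusted p = 0.134). Its call also ended without SAM/P-8 control replicate 1 (-0.64) and without SAM/P-8 CCH replicate 1 (-0.68). The mean of the meningeal list, 0.29, went to 0.09 without SAM/P-8 control replicate 4 (adjusted p = 0.254) and to 0.54 without control replicate 1. Its call also ended without SAM/P-8 CCH replicate 1 (0.18) and SAM/P-8 control replicate 2 (0.22). The oligodendrocyte precursor call also ended without SAM/P-8 CCH replicate 2 (0.10, adjusted p = 0.0509) and SAM/P-8 control replicate 1 (0.09, adjusted p = 0.0651). The mean of the glucocorticoid list went from 0.19 to 0.29 without SAM/P-8 control replicate 1. In total 250 probes were called, 146 higher and 104 lower with CCH, in 106 genes. The limma count was 0 with normexp, against 5548 probes at an unadjusted p under 0.05 in the fit as reported, and 28 when only the 8 SAM/P-8 arrays entered the fit. It ran from 72 to 438 as single arrays were left out, the extremes being SAM/P-8 control replicates 3 and 1.

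In SAM/R-1 the same 4 lists moved with CCH, with 0 of their members past the threshold. Immediate early genes rose, 22 of 24 with positive differences against 10.1 at equal brightness and a median of 0.39, 0 past the threshold and 13 adjusted over the list alone, with Egr4 at 0.51 ± 0.15 and Fos at 0.66 ± 0.20. For immediate early genes camera gave an adjusted p of 1.96e-10 (adjusted p = 0.343 with an estimated correlation). Clock genes rose, 17 of 19 with positive differences against 8.47 at equal brightness and a median of 0.23, 0 past the threshold and 9 adjusted over the list alone, with Per2, a core clock repressor, at 0.60 ± 0.12 (adjusted p = 0.0736, and 0.06 by its other probes), and Ciart at 0.51 ± 0.11. For clock genes camera gave an adjusted p of 5.71e-09 (adjusted p = 0.114 with an estimated correlation). Respiratory chain genes fell by a median of 0.06, 34 of 37 with negative differences, and ribosomal protein genes by 0.05, 33 of 37, against 24.2 and 24.5 at equal brightness. Of either list 0 genes passed the threshold or did so adjusted over the list alone, and camera gave adjusted p of 2.18e-04 and 0.0134 (adjusted p = 0.609 and 0.852 with an estimated correlation). Cox7c stood at -0.19 ± 0.06, Ndufa2 at -0.10 ± 0.04, Rps19 at -0.16 ± 0.06 and Rpl6 at -0.11 ± 0.06.

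Heat shock and chaperone genes rose in SAM/R-1 with 0 of 24 past the threshold and 2 adjusted over the list alone, Xbp1 at 0.33 ± 0.08 and Creld2 at 0.34 ± 0.09. For chaperone genes camera gave an adjusted p of 1.14e-06 (adjusted p = 0.388 with an estimated correlation). Cholesterol synthesis genes (Stard4 0.26 ± 0.09) and endothelial markers (Rgs5 0.39 ± 0.10, Flt1 0.40 ± 0.12) rose with 0 genes past the threshold and 0 and 2 adjusted over the list alone. Both had a camera adjusted p of 1.40e-04 (adjusted p = 0.550 and 0.609 with an estimated correlation). Glucocorticoid-responsive genes (Per1 0.43 ± 0.11, Hif3a -0.45 ± 0.08, turning to 0.08 with normexp), immature neuron markers (Ccnd2 0.20 ± 0.06, Draxin 0.14 ± 0.05) and meningeal markers (Fmod 0.85 ± 0.45, and Omd 1.02 ± 0.55 with 2 of 4 control arrays well above background) rose as lists with 0 genes past the threshold. Adjusted over the list alone they held 1 higher and 1 lower, 0 and 0 genes, and camera's adjusted p was 0.0267, 0.0267 and 0.0443 (adjusted p = 0.609, 0.343 and 0.852 with an estimated correlation). These 3 calls and that of the ribosomal list ended with quantile normalization. They also ended as single arrays were left out. The ribosomal mean went from -0.05 to -0.03 without SAM/R-1 CCH replicate 1 (adjusted p = 0.239), and the call also ended without SAM/R-1 CCH replicate 4 and SAM/R-1 control replicate 3. The immature neuron mean went from 0.14 to 0.08 without SAM/R-1 control replicate 1 (adjusted p = 0.0806) and to 0.09 without control replicate 4, and the call also ended without SAM/R-1 CCH replicate 1. The glucocorticoid call ended without SAM/R-1 CCH replicate 3 (mean from 0.14 to 0.10) and SAM/R-1 control replicate 3 (0.11). The meningeal mean went from 0.23 to 0.14 without SAM/R-1 control replicate 4 (adjusted p = 0.242) and to 0.37 without control replicate 2. That call also ended without SAM/R-1 CCH replicates 1 and 3, SAM/R-1 control replicates 1 and 3, and SAM/P-8 CCH replicate 4. The endothelial mean went from 0.17 to 0.10 without SAM/R-1 control replicate 4 and kept its call.

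Single genes of SAM/R-1 past the threshold were mostly lower with CCH and dim in the fit as reported. Bcor, a corepressor of BCL6, was 1.27-fold higher (0.34 ± 0.06, adjusted p = 0.0466), though its other probes gave -0.29. Foxe3, a transcription factor of lens development, was 1.85-fold lower (-0.89 ± 0.09, adjusted p = 0.00289), Bub1, a spindle checkpoint kinase, 1.82-fold (-0.87 ± 0.12), and the keratin gene Krt5 1.81-fold (-0.86 ± 0.12). F9, coagulation factor IX, was 1.91-fold lower (-0.93 ± 0.16) and Utf1 1.61-fold (-0.69 ± 0.12). Also lower were Sit1 (1.89-fold), the olfactory receptor gene Olfr1215 (1.78-fold), Spem2 (1.69-fold), Ly6g5c (1.58-fold) and the taste receptor gene Tas2r118, 1.91-fold with 2 of 4 CCH arrays well above background. In total 33 probes were called, 3 higher and 30 lower, in 14 genes, and with quantile normalization 40, 13 higher and 27 lower. The 30 had a median brightness at the 11.2th percentile of all probes, and 7 of them kept their direction with normexp. Foxe3, Sit1, Olfr1215, Spem2, Ly6g5c and Tas2r118 were among those that turned. The limma count was 0 with normexp, with 3156 probes at an unadjusted p under 0.05 in the fit as reported, and 2 without SAM/R-1 control replicate 3.

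**Figure D3:**
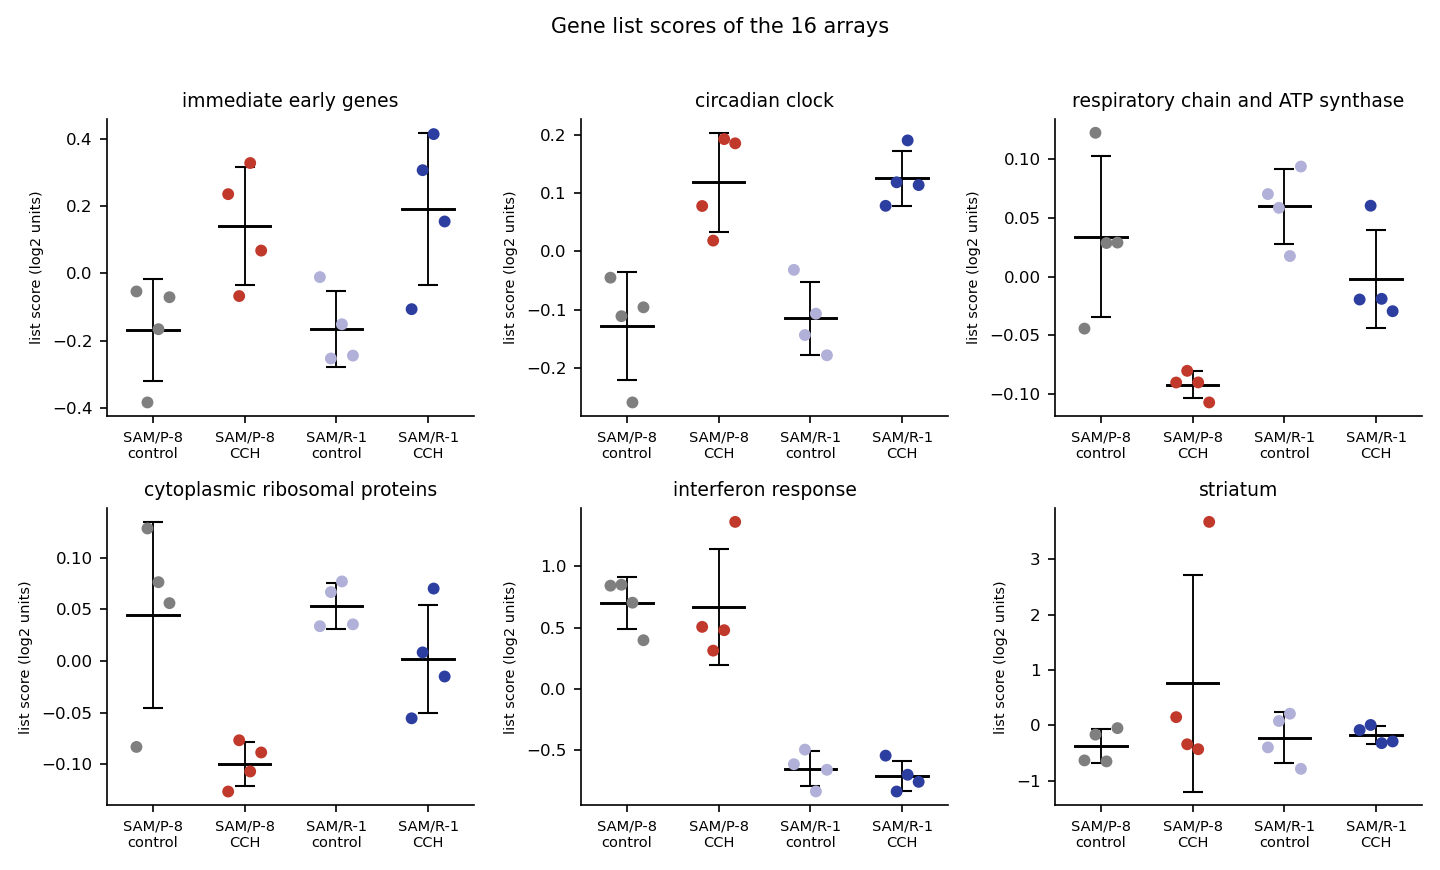
Mean level of the genes of 6 lists on each array, in log2 units relative to the mean of each gene over the 16 arrays. Each point is 1 array, with the mean and SD of 4 arrays in black, and the clock score was higher on all 4 CCH arrays than on all 4 control arrays in both strains, the interferon score separated the strains, and the striatum score of 1 SAM/P-8 CCH array stood at 3.68.

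The effect of CCH averaged over both strains used all 16 arrays. Immediate early genes rose, 8 of 24 with 0 lower and 18 adjusted over the list alone, with a median of 0.37. Egr2 rose 1.79-fold (0.84 ± 0.21, n = 8 and 8, adjusted p = 0.0397), Egr4 1.49-fold (0.57 ± 0.11), Arc, a synaptic plasticity gene, 1.47-fold (0.56 ± 0.13) and the nuclear receptor gene Nr4a1 1.46-fold (0.54 ± 0.12). For immediate early genes camera gave an adjusted p of 1.91e-10 (adjusted p = 0.339 with an estimated correlation). Clock genes rose, 7 of 19 with 0 lower and 11 adjusted over the list alone, with a median of 0.20. The repressors Cry1 (0.64 ± 0.12, adjusted p = 0.0141), Ciart (0.56 ± 0.08, adjusted p = 0.00453), Per2 (0.48 ± 0.08, adjusted p = 0.0116) and Per1 (0.45 ± 0.08, adjusted p = 0.0102) led, though the other probes of Per2 gave 0.01 (adjusted p = 0.990). For clock genes camera gave an adjusted p of 1.46e-09 (adjusted p = 0.0910 with an estimated correlation). Respiratory chain and ATP synthase genes fell, 6 of 37 with 0 higher and 18 adjusted over the list alone, with a median of -0.10. The genes in front were Ndufa2 (-0.19 ± 0.03), Cox7a2 (-0.18 ± 0.04), Ndufa4 (-0.15 ± 0.03) and Cox4i1 (-0.15 ± 0.03). For respiratory genes camera gave an adjusted p of 1.67e-09 (adjusted p = 0.405 with an estimated correlation). Cytoplasmic ribosomal protein genes had negative differences in 37 of 37 cases, where genes of equal brightness would give 28.6, with 3 lower and 21 adjusted over the list alone, Rps19 (-0.18 ± 0.04), Rpl35 (-0.16 ± 0.04) and Rpl37 (-0.15 ± 0.04), and a median of -0.10. For ribosomal genes camera gave an adjusted p of 2.58e-09 (adjusted p = 0.576 with an estimated correlation).

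Cholesterol synthesis genes rose with 5 of 22 past the threshold and 6 adjusted over the list alone. Among them were Insig1, a brake on sterol synthesis (0.33 ± 0.06), Lss (0.26 ± 0.06) and Stard4 (0.25 ± 0.06), though the other probes of Insig1 (0.17) and Stard4 (0.35) did not pass. For cholesterol genes camera gave an adjusted p of 2.89e-05 (adjusted p = 0.405 with an estimated correlation). Heat shock genes rose with 1 of 24 past the threshold, Hspa1b, an inducible chaperone (0.94 ± 0.23, adjusted p = 0.0395), and 5 adjusted over the list alone. For chaperone genes camera gave an adjusted p of 5.01e-06 (adjusted p = 0.405 with an estimated correlation). Proteasome genes fell with Psmb7 (-0.21 ± 0.05) and Psmc5 (-0.16 ± 0.04, but -0.02 by its other probes) as 2 of 27, 5 adjusted over the list alone. For proteasome genes camera gave an adjusted p of 7.41e-04 (adjusted p = 0.685 with an estimated correlation). Glucocorticoid-responsive genes rose with Per1, also in the clock list, as 1 of 15, and 4 higher and 1 lower adjusted over the list alone. For glucocorticoid-responsive genes camera gave an adjusted p of 0.00116 (adjusted p = 0.576 with an estimated correlation). In the senescence list Terf1 (0.21 ± 0.05) was higher and the DNA damage kinase gene Atm (-0.17 ± 0.04, but 0.00 by its other probes) lower, with 4 higher and 1 lower adjusted over the list alone. For senescence genes camera gave an adjusted p of 0.0246, upward (adjusted p = 0.199 with an estimated correlation). Neurotrophin genes rose with 0 of 17 past the threshold and 1 adjusted over the list alone (Fgf1 0.21 ± 0.06, but -0.01 by its other probes, and Fgfr3 0.18 ± 0.06). For neurotrophin genes camera gave an adjusted p of 0.0235 (adjusted p = 0.199 with an estimated correlation).

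Lists of other cell types and tissues moved as well with CCH on average. Meningeal markers (Col6a2 0.34 ± 0.10, Aldh1a2 0.70 ± 0.29), striatal markers, endothelial markers (Rgs5 0.27 ± 0.07, Tek 0.30 ± 0.11) and neocortical markers (Rorb 0.26 ± 0.10, Egr3 0.24 ± 0.09) rose with 0 genes past the threshold and 0, 0, 1 and 0 adjusted over the list alone. Of the neocortical markers given, Rorb is also in the clock list and Egr3 in the immediate early gene list, so these shifts are not separate. The striatal gene Gpr6 had 0 of 4 SAM/P-8 control arrays well above background and an adjusted p of 0.193. The 4 lists' camera adjusted p was 0.00393, 0.0108, 0.0165 and 0.0322 (adjusted p = 0.685, 0.740, 0.714 and 0.626 with an estimated correlation). Red blood cell genes fell with Slc4a1, the red cell anion exchanger, 2.69-fold lower (-1.43 ± 0.37) as 1 of 7, and 1 adjusted over the list alone. For red blood cell genes camera gave an adjusted p of 0.0342 (adjusted p = 0.685 with an estimated correlation). Quantile normalization ended the calls of the proteasome, red blood cell and neocortex lists, and leaving out SAM/P-8 CCH replicate 4 those of the striatum and endothelial lists (means from 0.60 to 0.11 and from 0.09 to 0.05). Other single arrays ended calls as well. The red blood cell mean went from -0.56 to -0.40 without SAM/P-8 control replicate 2 (adjusted p = 0.0815). That call also ended without SAM/P-8 control replicate 1, SAM/P-8 CCH replicate 1, SAM/R-1 CCH replicate 2 and SAM/R-1 control replicates 1 and 2. The meningeal mean went from 0.26 to 0.16 without SAM/P-8 control replicate 4 (adjusted p = 0.0518). The endothelial call also ended without SAM/P-8 control replicates 2 and 4 and SAM/R-1 control replicate 4 (0.05), and its mean was 0.13 without SAM/P-8 control replicate 1. The neocortex call ended without SAM/P-8 CCH replicate 3, SAM/P-8 control replicate 1, SAM/R-1 CCH replicate 3 and SAM/R-1 control replicates 2 and 4 (mean from 0.14 to between 0.12 and 0.15).

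Among single genes, the largest average increases with CCH were those of Asb9 (with 0 to 1 of 4 arrays well above background in the groups other than SAM/P-8 CCH, so its size is not measured), Hspa1b, Egr2, the small GTPase gene Gem (0.82 ± 0.18) and the kinase gene Sik2 (0.73 ± 0.14, adjusted p = 0.0171). The largest decreases were those of AY761185 (-1.64 ± 0.17, adjusted p = 3.31e-04), Slc4a1, Olfr1263 (-1.09 ± 0.17), the homeobox gene Tlx2 (2.00-fold, n = 6 and 8) and the kallikrein gene Klk9. Tlx2 had 2 values in SAM/R-1 CCH, and its call ended as 9 of the 16 arrays were left out in turn. Klk9 had 1 to 4 of 4 arrays well above background per group, so its size is not measured, and it turned to 0.15 with normexp. In total 1206 probes were called, 604 higher and 602 lower, in 560 genes. The count was 111 with normexp, where 462 of the 602 lower probes kept their direction, and 3346 without the filter on dim probes. It ran from 297 to 2143 as single arrays were left out, the extremes being SAM/P-8 control replicates 3 and 1.

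The 2 CCH effects shared no arrays and were positively correlated. Over 13458 genes they correlated with Pearson's r = 0.302 and Spearman's rho = 0.451, genes not being independent replicates, and 94 of the 106 genes called in SAM/P-8 had the same sign in SAM/R-1. The share of equal signs over all genes was not counted beside it. Genes as bright as the 37 ribosomal ones would give 30.2 negative differences in SAM/P-8 and 24.5 in SAM/R-1. A shift that follows the signal level may thus hold part of this agreement. Bcor and Foxe3 were called in both strains: Bcor rose in both by the probe used, and Foxe3 rose in SAM/P-8 (0.52 ± 0.09, with 1 of 4 control arrays well above background) and fell in SAM/R-1 (-0.89 ± 0.09), where it turned to 0.15 with normexp, so that the opposite directions ended.

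**Figure D4:**
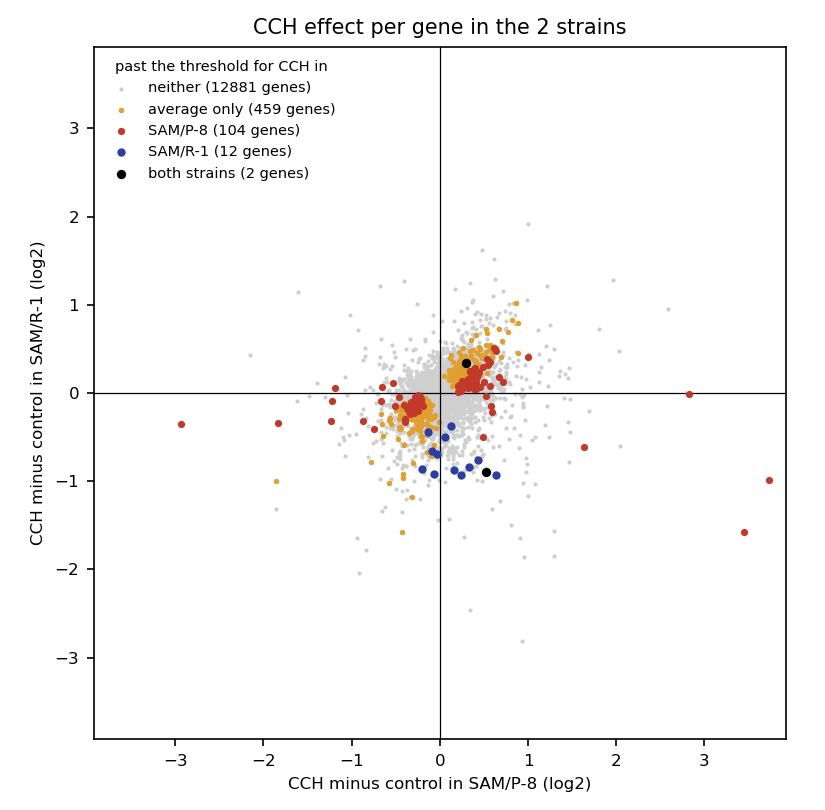
Log2 difference between the CCH and the control diet per gene, in SAM/P-8 (horizontal axis) and in SAM/R-1 (vertical axis), for 13458 genes. Colours mark the 104 genes past the threshold in SAM/P-8 alone, 12 in SAM/R-1 alone, 2 in both and 459 in the average of the strains alone. Of the 106 genes called in SAM/P-8, 94 had the same sign in SAM/R-1, and the share over all genes was not counted.

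The strain by diet interaction asked which CCH effects differed between the strains. AY761185 fell with CCH in SAM/P-8, from -2.03 ± 0.10 to -4.96 ± 0.68 (mean ± SD, n = 4 each), while it stood at -4.51 ± 0.15 and -4.87 ± 0.20 in SAM/R-1 (interaction -2.58 ± 0.34, adjusted p = 0.00353). Stc1 fell in SAM/P-8 from -3.17 ± 0.12 to -3.82 ± 0.07 against -3.85 ± 0.08 and -3.78 ± 0.17 in SAM/R-1 (interaction -0.73 ± 0.11, adjusted p = 0.0152), though its other probe gave 0.27. The 5 largest positive interactions were those of Krt35, Olfr103, Elf4, Nat3 and Olfr1317, with adjusted p from 0.0134 to 0.0442, and each had at least 1 group with 0 arrays well above background, so their sizes are not measured. Krt35 had 3 values in SAM/P-8 CCH. In total 50 probes were called, 39 up and 11 down, in 18 genes, and with quantile normalization 32, 19 up and 13 down. The 39 had a median brightness at the 4.38th percentile. The limma count was 0 with normexp, with 1627 probes at an unadjusted p under 0.05 in the fit as reported.

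Lists shifted in the interaction without any single member past the threshold or adjusted over the list alone. Ribosomal protein genes (median -0.09, Rpl19 -0.23 ± 0.07, Rps9 -0.17 ± 0.07), respiratory chain genes (median -0.07, Ndufa2 -0.18 ± 0.06, Cox4i1 -0.12 ± 0.06), proteasome genes (median -0.06, Psmb4 -0.15 ± 0.07, Psmb7 -0.15 ± 0.09) and endothelial markers (median -0.16, Flt1 -0.46 ± 0.17, Ly6c1 -0.41 ± 0.19) had the more negative CCH effect in SAM/P-8. Camera's adjusted p was 8.22e-07, 4.59e-04, 0.0111 and 0.0114 (adjusted p = 0.940 for each with an estimated correlation). Striatal (median 1.14, Ido1 2.64 ± 1.30, Ppp1r1b 1.27 ± 0.86), dopamine (median 0.60, Ppp1r1b again, Maoa -0.10 ± 0.06), pituitary hormone (median 0.21, Pomc 0.12 ± 0.08, and Trh with 0 of 4 SAM/P-8 control arrays well above background) and oligodendrocyte precursor genes (median 0.12, Neu4 0.29 ± 0.12, Sapcd2 0.25 ± 0.11) had the more positive one. Here camera's adjusted p was 4.59e-04, 0.0114, 0.0114 and 0.0246 (adjusted p = 0.940 for each with an estimated correlation). Genes as bright as the ribosomal, respiratory and proteasome ones would give 30.2, 29.9 and 20.5 negative CCH differences in SAM/P-8. In SAM/R-1 they would give 24.5, 24.2 and 16.9. A shift that follows the signal level may thus hold part of the interactions of these lists. Without SAM/P-8 CCH replicate 4 the number of lists fell to 4, none of them upward, and the proteasome call ended too (mean from -0.06 to -0.04). The endothelial mean went from -0.17 to -0.08 without SAM/P-8 control replicate 1 (adjusted p = 0.549) and to -0.10 without SAM/R-1 control replicate 4. That call also ended without SAM/P-8 CCH replicate 2 (-0.11) and SAM/R-1 CCH replicate 1 (-0.13). The respiratory mean went from -0.06 to -0.03 without SAM/P-8 control replicate 2 and kept its call. Without SAM/R-1 control replicate 3 the proteasome (-0.04), pituitary hormone (from 0.60 to 0.40) and oligodendrocyte precursor (from 0.10 to 0.06) calls ended. The last also ended without SAM/P-8 control replicate 3 and SAM/R-1 CCH replicates 2 and 4. Quantile normalization left 3 of the lists.

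The last comparison asked whether CCH moved SAM/P-8 towards or away from the levels of SAM/R-1. The strain difference on the control diet and the CCH effect in SAM/P-8 share the SAM/P-8 control arrays, which alone push them apart. Of 830 genes higher in SAM/P-8 than in SAM/R-1 on the control diet and 50 lower with CCH in SAM/P-8, 7 were in both groups: Adamts14, AY761185, Mt3, Npb, Olfr1263, P2ry6 and Stc1. Among them Mt3, a neuronal metallothionein, fell by 0.33 ± 0.07 and P2ry6, a nucleotide receptor gene, by 0.37 ± 0.08. Of 896 genes lower in SAM/P-8 and 56 higher with CCH, 13 were in both, including Ciart, Nat3, Tert and Vipr1. Lists of these sizes shared 23.6 and 27.4 genes on average in 100 simulations without effects and with shared controls, and independent lists would share 3.08 and 3.73. In contrast 6 genes were lower in both contrasts, Lrp2 and Mc2r among them, and 0 higher in both, against 0.02 and 0.01 simulated and 3.33 and 3.45 for independent lists. The simulations held no strain differences, so noise in the arrays alone picked their genes. They can overstate the overlap in opposite directions that shared controls would give here. That 7 and 13 lay under 23.6 and 27.4 therefore decides nothing. With the control arrays split into 2 and 2 the opposite directions shared 4.33 and 3.17 genes on average over the 6 ordered splits. Independent lists would share 1.22 and 0.963. The same directions shared 1.67 lower and 0.667 higher, against 1.24 and 0.955. Both parts of each split lay on the same slide, so a difference of that slide could still give opposite directions. Over 13458 genes the correlation was -0.138 (Spearman's rho = -0.097), against -0.498 in 100 simulations of the whole table without effects, between -0.565 and -0.433, so it lay outside their range. Real strain differences add spread that weakens a correlation and leaves the covariance from the shared arrays as it is. Opposite signs made up 51.8% of genes against 66.7% simulated. The correlation was 0.04 on average over the 6 ordered splits of the control arrays into 2 and 2, between -0.04 and 0.13. The covariance was -0.0105 against -0.0115 simulated, which lay between -0.0139 and -0.00954, so it was inside the range that the shared control arrays give alone.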

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

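The tests of the background estimate, of slides that hold both diets, of genes with 1 probe and of the tissue scores were chosen after the result was seen, the permutation of list scores was added after random splits had matched the number of lists, and the strain differences were divided by number of probes after the share of agreeing probes was known.

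The immediate early gene and clock lists rose and the ribosomal and respiratory lists fell with CCH on average, and values follow in this order. All 4 list calls are lost with an estimated correlation (adjusted p = 0.339, 0.0910, 0.576 and 0.405). Genes of equal brightness argue against a shift that follows the signal level as the whole cause, since the medians lay at percentiles 100, 100, 0.2 and 0.06 of 10000 matched random lists. For the ribosomal and respiratory lists the random lists had medians of -0.0583 and -0.0567 against -0.0967 and -0.0982, and the lowest stood at -0.105 and -0.113. These 2 shifts thus lie in large part in genes of equal brightness, and the values argue against the signal level only as their whole cause. With the choroid plexus and striatum scores in the fit the mean shifts kept 0.874, 0.881, 1.10 and 1.01 of their size and the calls stayed, which argues against these tissues in the dissections as the whole cause. Exact permutation of diet within strain over 4900 relabellings (two-sided) gave p = 0.00204, 0.000408 (the smallest it can give), 0.00612 and 0.00163, and 0.00272, 0.00163, 0.00612 and 0.00272 after Benjamini-Hochberg over the 4 lists, which were picked for their calls. The number of slides that held both diets was 0, so a difference between slides that moves these genes cannot be told apart from the diet. The same holds for any other difference between the groups in how the samples were taken or handled. The diet stays open as 1 possible explanation among these.

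Of 235 genes with a strain difference of at least 2-fold on the control diet, 44 had another probe. In 27 of these, 61.4%, it passed in the same direction, and in 6 in the opposite one, against 10.5% in the same direction among all genes with several probes, which argues against sequence variants under single probes as the whole cause for these 44 genes; overlap between probe sequences was not checked. For the 191 genes with 1 probe kept, a variant under the probe cannot be told apart from a difference in level. Called genes were followed along the chromosome by another called gene in 19.1% of cases, against 10.4 to 15.8% in 1000 shuffles, so chromosome blocks that differ between the strains may hold part of the differences, as a hypothesis.

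With normexp in place of the scanner software's background estimate, 7 of the 30 probes called lower with CCH in SAM/R-1 kept their direction, and 146 of the 146 called higher in SAM/P-8. The background estimate near the detection limit is thus a candidate explanation for the decreases in SAM/R-1, whose median brightness was at the 11.2th percentile, and the values argue against it as the source of the direction in SAM/P-8, although 0 of those probes passed with normexp. An effect of the diet on these dim genes in SAM/R-1 stays open.

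Other splits of the arrays were counted for each comparison, with all 16 arrays in the fit for real and other splits alike, and 1 split is the smallest count possible. For the number of probes no other split reached the count of the real one. The real split, 1 of 35, gave 4004 for the strain difference on the control diet (highest other 2) and 3909 on the CCH diet (1). It gave 250 for the CCH effect in SAM/P-8 (35) and 33 in SAM/R-1 (1). For the average 1 of 100 reached 1206 (521), and for the interaction 50 (22). The probes had been kept by the real groups and not anew for each split, which can favour the real split for dim probes. Of the 39 probes called up in the interaction, 14 were well above background on all 16 arrays. These counts thus argue against chance but cannot exclude it, above all for dim probes. In a test added after the result was seen, with only the 8 arrays compared in the fit, the real split was again 1 of 35, with 3266, 2870, 28 and 24 probes (highest other 1, 0, 0 and 0). For the number of gene lists chance cannot be excluded. With the real split included, 6, 9, 14 and 10 lists were reached by 33, 30, 21 and 10 of 35 splits (highest other 15, 17, 20 and 15). The 15 lists of the average were reached by 18 of 100 (19) and the 8 of the interaction by 85 of 100 (22).

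A sample stood apart from the 3 others of its group in 15 of 222 groups tested, where chance gives about 1 in 20, or 11.1. SAM/P-8 CCH replicate 4 stood apart in the striatum score, 3.68 against -0.43 to 0.15, the dopamine signalling score, 2.53 against -0.26 to -0.01, and the score of pituitary and hypothalamic hormones, 1.32 against -0.25 to -0.01. In SAM/R-1 CCH the slope of the spike-in controls of replicate 1 was 0.906 against 0.957 to 0.963, the respiratory score of replicate 2 was 0.0604, the cholesterol synthesis score of replicate 4 was -0.0401 and Gem in replicate 3 was at -2.42. In SAM/R-1 control Ccl19 in replicate 2 was at -0.10, Olfr1263 in replicate 2 at -3.15 and Slc7a9 in replicate 4 at -2.92. In SAM/P-8 control Gdpd5 in replicate 1 was at -2.83 and Cenph in replicate 4 at -4.29, and in SAM/P-8 CCH Prdm16 in replicate 1 was at -1.76, Nat3 in replicate 1 at -4.19 and Ciart in replicate 3 at -1.17.

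The CCH effect differed between the strains, by the interaction term, for 50 probes. Named genes had fitted interactions of 5.03 (Krt35), 2.86 (Olfr103), 2.31 (Elf4), 2.24 (Nat3), 1.87 (Olfr1317), -2.58 (AY761185) and -0.73 (Stc1), the 5 positive ones with a group at background, so that their sizes are not measured, and Krt35 with 3 values in SAM/P-8 CCH. Lists had medians of -0.0905 (ribosomal), -0.0652 (respiratory), -0.0625 (proteasome), -0.16 (endothelium), 1.14 (striatum), 0.60 (dopamine), 0.21 (pituitary hormones) and 0.12 (oligodendrocyte precursors). With an estimated correlation 0 of these lists passed. Genes as bright as the ribosomal, respiratory and proteasome ones also had negative differences more often in SAM/P-8 than in SAM/R-1. Without SAM/P-8 CCH replicate 4 the striatum, dopamine, pituitary hormone, oligodendrocyte precursor and proteasome calls ended.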

How the results depend on the processing

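Normexp with trend and robust and the covariate fit were chosen after the data were seen; the cause was not tested for any change given here, except that by construction a minimum of 1.5-fold raises the size a call must reach, fewer arrays in the fit use fewer samples and 1 probe per gene tests fewer items. Of the calls of named genes, the authors' table kept 144 and ended 3, quantile normalization kept 124 and ended 23, and normexp kept 41 and ended 97, besides 9 that turned. Normexp with trend and robust kept 64 and ended 74, besides the same number that turned. The covariates kept 93 and ended 54, only the groups compared 73 and 35, the replicate block 124 and 23, no filter 126 and 21, a minimum of 1.5-fold 100 and 47, trend and robust 138 and 9, array weights 142 and 5, 1 probe per gene 146 and 1, and only probes well above background on all 16 arrays 97 and 2. The other probes of a gene kept 17, ended 9 and turned 4. Leaving out each array in turn kept the call in 1862 pairs of call and array and ended it in 490. Of 62 calls of lists the authors' table and the replicate block kept 62, quantile normalization 46 and fry 17. The covariates kept 47 of the 58 run, without the 4 calls of the striatum list, whose score is a covariate. Dim signal limits the CCH effect in SAM/R-1 and the interaction most, with median brightness of the calls at the 11.2th percentile (lower) and the 4.38th (higher).

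Quantile normalization gave 143 probes for the CCH effect in SAM/P-8, 40 in SAM/R-1, of which 13 were higher and 27 lower against 3 and 30 as reported, 32 for the interaction, 19 up and 13 down against 39 and 11, and 6 and 3 lists for SAM/R-1 and the interaction. Normexp gave 962 and 840 probes for the strain difference on the control and the CCH diet, 0 for SAM/P-8, 0 for SAM/R-1, 111 for the average and 0 for the interaction. Together with trend and robust it gave 1334, 1261, 112, 1 and 2 for the strain differences, SAM/P-8, SAM/R-1 and the interaction. At an unadjusted p under 0.05 the limma fit as reported held 5548, 3156 and 1627 probes for SAM/P-8, SAM/R-1 and the interaction. Without a filter 152 probes were called in SAM/P-8 and 3346 on average, and with all 16 arrays well above background 17 in SAM/R-1 and 17 in the interaction. With only the groups compared, 28 were called in SAM/P-8, and with trend and robust 9 in SAM/R-1. With 1 probe per gene counts were 1780, 1773, 142, 19, 776 and 16 genes, and with at least 1.5-fold 1393, 1166, 57 and 66 for the strain differences, SAM/P-8 and the average. Array weights gave 142 in SAM/R-1 and 2459 on average, and covariates 58, 14 and 204 for SAM/P-8, SAM/R-1 and the average, with 4 lists in the interaction.

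The replicate block gave 132 probes in SAM/P-8 and 20 in SAM/R-1, and 3757, 3664, 883 and 35 for the strain differences, the average and the interaction. Deviations of same-number arrays from their group means correlated at 0.00626 on average over 24 pairs, from -0.249 to 0.303. No pattern common to arrays of the same number was thus seen, which does not settle whether the numbers pair the samples.

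With an estimated correlation 0, 0, 0, 0, 0 and 0 lists passed, with 4, 1, 3, 5, 5 and 0 at an unadjusted p under 0.05. With fry 2 passed for the strain difference on the CCH diet, 4 in SAM/P-8, 1 in SAM/R-1, 6 on average and 0 in the interaction. The relation between the strain difference and the CCH effect was -0.298 without a filter and 0.0396 with split controls.

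Direction turned with normexp, also with trend and robust, for Accsl in SAM/P-8 (0.023), for Tas2r118 (0.26), Sit1 (0.12), Foxe3 (0.15), Olfr1215 (0.24), Spem2 (0.000547), Ly6g5c (0.19) and Hif3a (0.0813) in SAM/R-1, for Klk9 on average (0.15) and for Itgam between strains on the CCH diet (-0.0229). With the other probes of the gene it turned for Stc1 (0.22 in SAM/P-8, 0.27 in the interaction), Bcor in SAM/R-1 (-0.29), H2-D1 between strains on the CCH diet (-0.0138) and Fgf1 on average (-0.00618). With covariates the dopamine list in SAM/P-8 turned to -0.0292.

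Leaving out each array in turn gave 2973 to 4521 and 2821 to 4158 probes for the strain differences, 72 to 438 for SAM/P-8, 2 to 43 for SAM/R-1, 297 to 2143 for the average and 35 to 55 for the interaction, and 4 to 6, 9 to 12, 12 to 19, 8 to 13, 13 to 17 and 4 to 11 lists. In SAM/P-8 the count was 112, 128, 85 and 93 without SAM/P-8 CCH replicates 1 to 4, 438, 73 and 72 without SAM/P-8 control replicates 1, 2 and 3, 141 and 144 without SAM/R-1 CCH replicates 1 and 4, and 163 and 157 without SAM/R-1 control replicates 1 and 3. In SAM/R-1 it was 14 and 8 without SAM/R-1 CCH replicates 2 and 3, and 19, 11 and 2 without SAM/R-1 control replicates 1, 2 and 3. On average it was 401 and 572 without SAM/P-8 CCH replicates 1 and 3, 2143, 347 and 297 without SAM/P-8 control replicates 1, 2 and 3, 383, 421 and 535 without SAM/R-1 CCH replicates 1, 3 and 4, and 544, 352 and 546 without SAM/R-1 control replicates 2, 3 and 4. The interaction had 4 lists without SAM/P-8 CCH replicate 4, and the striatum list between strains on the CCH diet, 0.94 as reported, ran from -0.0356 without that array to 1.33. The relation ran from -0.271, without SAM/P-8 control replicate 4, to -0.089. A slide block was not run, since slide and group coincide, nor were only the groups compared for the average and the interaction, which use all groups.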

Other observations

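The gene lists were fixed before the data were examined, and the runs of neighbouring genes were picked for description after the result was seen. Of the 42 gene lists 20 passed in none of the 6 comparisons. For the 27 genes of NRF2 and antioxidant defence the median was 0.02 between strains on the control diet, with 1 gene higher and 2 lower, and -0.00336 with CCH on average, with 0 genes past the threshold. The 20 genes of the amyloid, tau and lipoprotein list had medians of -0.03 and -0.0347 in these comparisons, with 1 higher and 1 lower between strains and 0 with CCH. Glycolysis came closest to the threshold, with a median of -0.09 for CCH in SAM/P-8, 0 of 20 genes past the threshold and a camera adjusted p of 0.0543.

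Markers of the hippocampal neurons gave 0 calls of lists. With CCH on average the medians were -0.07 for CA1 pyramidal cells, with 1 of 15 genes lower and 5 adjusted over the list alone, -0.0449 for CA2 and CA3 pyramidal cells, with 1 of 16 lower, and -0.0754 for dentate granule cells, with 1 of 15 lower. Choroid plexus markers had a median of -0.65 with CCH on average and 0 of 19 genes past the threshold, at a camera adjusted p of 0.217. Their score lay between -2.68 and -1.26 on 5 arrays, SAM/P-8 CCH replicate 3, SAM/P-8 control replicate 4, SAM/R-1 CCH replicates 2 and 3 and SAM/R-1 control replicate 4, and between 0.21 and 1.64 on the other 11. The average score difference between the diets, -0.704, was -0.258 without SAM/P-8 CCH replicate 3, -0.416 without SAM/R-1 CCH replicate 2 and -1.09 without SAM/P-8 control replicate 4.

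Genes called between the strains on the control diet stood in runs along some chromosomes. On chromosome 17 there were 7 neighbours from Atp6v1g2 to Tcf19, in the H2 region, 5 higher and 2 lower in SAM/P-8. On chromosome 7 there were 9 from Aurkc to Zfp606, including Zfp551, 4 higher and 5 lower. Of 299 pairs of neighbours both called, 172 had the same direction.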
